A study of Mus musculus with 2 samples.

How the data were processed

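Gene expression was measured on 2 Affymetrix mouse expression arrays. Per the labels, each array was hybridised with biotin-labelled cRNA made from 3 µg of total RNA by the manufacturer's standard protocol. The RNA came from mIMCD-3 cells, a mouse line derived from the inner medullary collecting duct of the kidney, 24 hours after infection with adenovirus. The cells of 1 array received a control adenovirus and those of the other an adenovirus carrying KLF5. Each group therefore held 1 array.

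The deposited values are linear intensities, with 1 value for each of 45101 probe sets on each array. They are not on a log scale, and their lowest and highest values were 0.0653 and 36466 on the control array and 0.209 and 41897 on the array labelled KLF5. The mean intensity without the lowest and highest 2% of probe sets was 500.003 on both deposited arrays, which shows a global scaling to a common trimmed mean by the authors. The software, the background correction and any detection calls are not given in the sources used here. No column of other samples was present. The number of arrays limits the precision of every value. With 1 array per group there is no replicate error, so no p-value was computed for any gene or gene list.

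Probe sets were named from the platform's annotation. It gave exactly 1 gene for 34958 probe sets, several for 932 and none for 9211. Of the manufacturer's 64 control probe sets 51 had no gene, and 13 named 1 of 4 genes and were kept with the others, so that Actb and Gapdh were read from such a probe set. Entrez identifiers were looked up in the RefSeq gene table of mouse assembly GRCm38.p6. Of the probe sets with 1 gene, 34754 were found there and 204 kept the symbol of the annotation. No symbol changed. Probe sets with several genes or none were left out of all gene results. No coordinates are given because the array files name no genome build.

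Intensities were brought to log2. The median of all probe sets was 49.5 on the control array and 55.1 on the array labelled KLF5, a difference of 0.15 on the log2 scale. Because this exceeded a limit of 0.1 set in advance, each array was centred on its median. This lowers every log2 ratio by the same 0.15 against the deposited scaling, so that a printed log2 ratio is that much below the ratio of the deposited intensities printed beside it. The median log2 ratio of all measured genes was -0.16 after centring and -0.01 as deposited. The median of a gene list relative to all measured genes is therefore its printed median plus 0.16. It is written out for the interferon, S100, mitotic and mesenchymal lists and for an alternative of the chemokine list.

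A probe set counted as measured when it lay above the array's 50th percentile on at least 1 array. Values under that percentile were set to it, and a ratio with such a value on 1 side is a lower bound on the centred scale, written as "at least". A bound on a fall can exceed the ratio of the deposited intensities where the dimmer value lies close to the floor. A gene with several measured probe sets took the brightest by mean level. This left 21660 probe sets and 11938 genes. The log2 ratio is the array labelled KLF5 over the control array. A gene was called higher or lower at a change of 2-fold or more, a size rule and not a test.

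Gene lists for the cell line, other cell types, inflammation, the response to virus, proliferation, stress, signalling and metabolism were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. For each list, the median log2 ratio of its measured members was placed among 10000 random lists of the same size matched on mean level in 20 bins. The percentile describes these 2 arrays and is not a test of the conditions. The rule named Klf5, the 12 genes with the largest rise and the 12 with the largest fall whose measured probe sets moved the same way and that have more than a clone or model name, up to 4 members past 2-fold in each list (or the 2 with the largest change where none passed), and S100a8, S100a9, Ccl2, Cxcl1, Cdh1, Aqp2 and Pdgfa.

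As the nearest substitute for an error, the log2 ratios of the brightest and the next brightest measured probe set were compared in the 5698 genes that had both. This covers differences between probes and not between cultures. The steps were tested on simulated data made from the control array with 200 genes changed by known folds, assuming noise with an SD of 0.25 above the median and 1.0 below it. Among 12022 genes, 50 were changed for each fold (3 or 8) and direction, all taken from the brighter genes. Of these, 96% of genes raised 3-fold and 98% of genes lowered 3-fold were called, as were 100% of those changed 8-fold. Recovery was not tested for genes near the floor, so these rates do not describe calls there. Of the unchanged genes, 2.04% were called. This rate follows from the assumed noise and includes no difference between cultures, so it is not the rate of false calls between the 2 real arrays. Of 100 random lists, 6 fell outside the central 95%.

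Alternatives were other floors (the 40th and 60th percentile, or none), quantile normalization, a loess correction of the ratio against level, the mean of a gene's probe sets, only probe sets without the _s_at or _x_at suffix, a pseudocount of 32, and thresholds of 1.5-fold and 3-fold. The deposited scaling was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used.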

Results

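The response of collecting duct epithelial cells to an adenovirus described as carrying KLF5, a zinc finger transcription factor, was profiled in mIMCD-3 cells. The single comparison was between 1 array of cells infected with that virus and 1 array of cells infected with a control adenovirus, both 24 hours after infection. Nothing was replicated, so the values below carry no SD and no p-value, and differences between these 2 arrays cannot be separated from differences between cultures. The log2 intensities of all 45101 probe sets correlated with r = 0.91 between the arrays, and those of the 20837 probe sets above the median on both with r = 0.96. These correlations are across probe sets, which are not independent replicates. In the 5698 genes with more than 1 measured probe set, the log2 ratios of the brightest and the next brightest probe set differed with an SD of 0.41 and had the same sign in 78.2% of genes.

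The Klf5 transcript was not higher on the array labelled KLF5. Its brightest probe set read 2179 on the control array and 1766 on the array labelled KLF5, a log2 ratio of -0.46, about the size of the spread between probe sets. A dimmer probe set read 98.9 and 73.6, with a log2 ratio of -0.58, and another read 28.1 and 19.7, below the median of both arrays. The sources used here do not say which species or which part of the KLF5 transcript the virus carried, nor which part of Klf5 the probe sets cover, so a transgene outside the probed sequence would not be seen. The transcript level therefore does not check the labels, and every direction below rests on the array's label alone. None of the 19 measured members of the KLF and SP family changed by 2-fold, and the largest changes were those of Klf10 (log2 ratio 0.76) and Klf16 (log2 ratio 0.72). With the floor at the 40th percentile 1 of 21 was at least 2-fold higher, and without a floor 2 of 22.

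Of 11938 measured genes, 502 were at least 2-fold higher on the array labelled KLF5 and 485 at least 2-fold lower, and 39 and 25 of them differed by 8-fold or more. The rises were led by genes of stratified epithelia and the falls by genes of the interferon response. S100a9, which encodes a calcium-binding protein released by neutrophils and stressed epithelia, showed the largest rise, from 3.67 to 8525, at least 155-fold. Suprabasin (Sbsn), dermokine (Dmkn), Krtdap and Slurp1, all genes of differentiating keratinocytes, followed with rises of 85.6-fold, at least 74.8-fold, at least 71.0-fold and at least 41.7-fold. The uroplakin genes Upk1b and Upk3b, whose products coat the bladder surface, rose 30.7-fold and at least 20.4-fold. Also among the 12 largest rises were Mal, encoding a protein of apical membrane sorting (at least 28.0-fold), and the stomach gene Gkn2 (at least 27.0-fold). The others were Calr3 (25.2-fold), the growth factor carrier Fgfbp1 (23.7-fold) and the intracellular chloride channel gene Clic3 (19.9-fold, or 9.83-fold with the floor at the 60th percentile). Every measured probe set of Sbsn, Upk1b, Upk3b, Mal and Calr3 moved the same way, which the rule for these genes required. Those of Upk1b ranged from a log2 ratio of 2.10 to 4.94. The Upk3b probe sets and the brighter one of Mal were under the floor on the control array, so they could only rise. With the mean of probe sets Upk1b rose 15.1-fold and Calr3 13.7-fold. S100a9, Dmkn, Krtdap, Slurp1, Gkn2, Fgfbp1 and Clic3 were each measured by a single probe set.

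**Figure D1:**
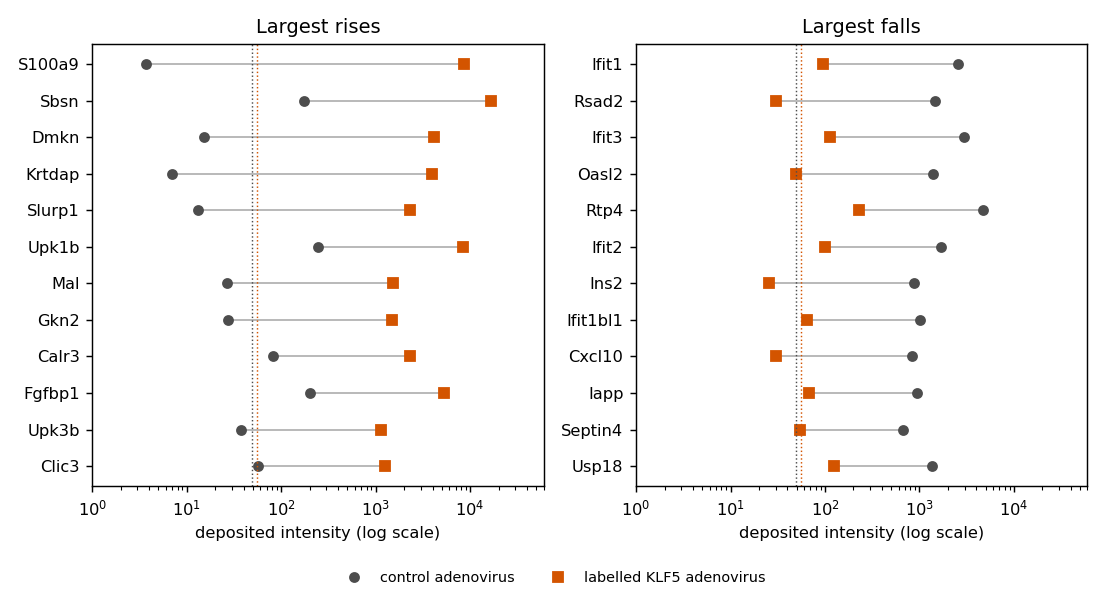
Deposited intensities (log axis) of the 12 genes with the largest rise and the 12 with the largest fall by the fixed rule, on the control array (circles) and the array labelled KLF5 (squares), 1 array each and without error bars. Dotted lines mark each array's median, 49.5 and 55.1, under which values were treated as a floor. S100a9 went from 3.67 to 8525 and Ifit1 from 2561 to 96.0.

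The largest falls were in genes induced by interferon. Ifit1 fell 29.7-fold, from 2561 to 96.0, and Ifit3 fell 29.4-fold, from 2980 to 112.8. Rsad2, which encodes the antiviral protein viperin, fell at least 29.5-fold, with 3 probe sets moving the same way, as the rule required. Oasl2 (at least 28.2-fold), Rtp4 (22.7-fold), Ifit2 (18.8-fold), Ifit1bl1 (17.1-fold, or 9.36-fold with the floor at the 60th percentile), the chemokine gene Cxcl10 (at least 16.8-fold) and Usp18 (12.2-fold) were also among the 12. Ifit1 and Ifit1bl1 belong to a family of similar sequences, so their signals may not be fully separate. The remaining members of the 12 were Septin4 (13.5-fold or more after centring, 12.1-fold or more as deposited) and the islet hormone genes Ins2 (at least 17.6-fold, from a probe set whose suffix marks possible cross-hybridisation) and Iapp (15.2-fold). With the mean of probe sets, which takes in dimmer ones at the floor, the falls were smaller for Rsad2 (14.6-fold), Rtp4 (11.05-fold), Septin4 (8.85-fold) and Iapp (6.06-fold).

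A measure of reliability comes from genes with more than 1 probe set. Of 179 genes called higher that had another measured probe set, the next brightest probe set was also higher in 170 and passed 2-fold in 116. Of 201 genes called lower, it was also lower in 188 and passed 2-fold in 111. Across all 5698 genes, the next brightest probe set passed 2-fold upward in 2.93% and downward in 3.93%. In 127 of the higher and 84 of the lower genes the dimmer array was at the floor, so that the fold is a bound. The share of higher genes among all calls depended on the scaling, at 50.9% after centring, 65.3% as deposited, 64.8% after loess, 63.2% after quantile normalization and 64.8% with the pseudocount. The deposited scaling adds the same 0.15 to every log2 ratio, so it could end no higher call, and 349 of the 485 lower calls remained under it.

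**Figure D2:**
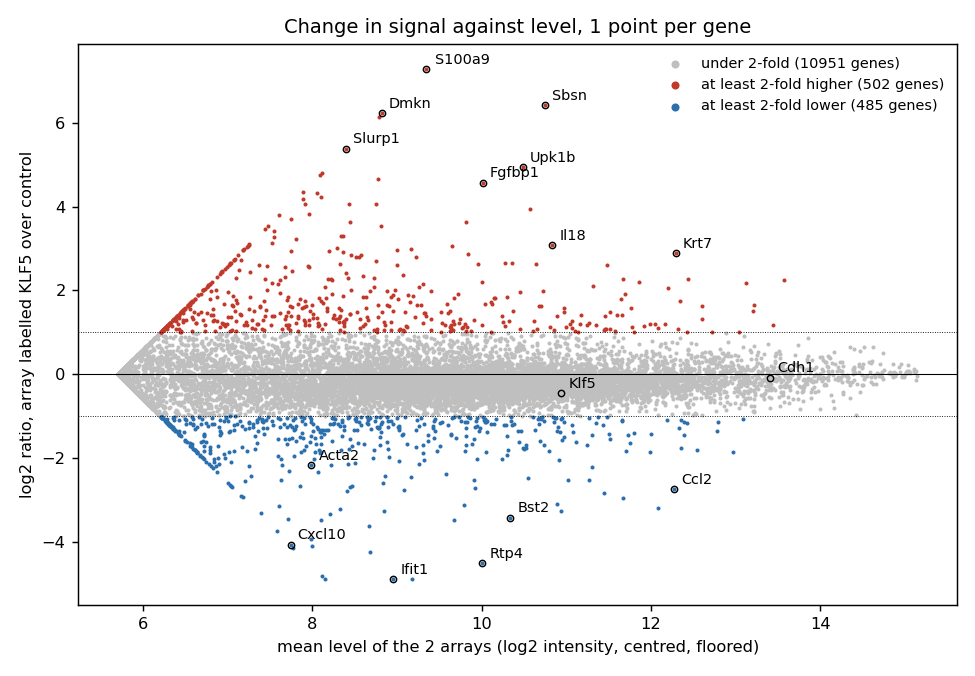
Log2 ratio of the array labelled KLF5 over the control array (vertical axis) against the mean log2 intensity of the 2 arrays after centring and flooring (horizontal axis), with 1 point for each of 11938 genes and no replicate error. The straight edges at low levels are genes at the floor on 1 array, and dotted lines mark 2-fold. Klf5 lies among the uncalled genes at -0.46.

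Genes of the interferon response were lower as a group. Of the 32 measured members of the fixed list, 26 were at least 2-fold lower, none was higher and 6 were not called. The median log2 ratio was -2.01, or -1.85 relative to all genes, and lay at percentile 0 of the random lists. Beyond the leading genes, this held for antiviral effectors such as Bst2 (log2 ratio -3.42) and for Irf7 (log2 ratio -1.98), a transcription factor of the response. It also held for the immunoproteasome genes Psmb8 (log2 ratio -2.01) and Psmb9 (log2 ratio -2.08). Mx1 was the only measured member with a positive log2 ratio, 0.67. B2m, also a common reference gene, fell short of the 2-fold limit with a log2 ratio of -0.82. Bst2, Irf7, Psmb8, Psmb9 and Mx1 lay outside the rule for named genes and were chosen after their values were seen. These values were taken from cells that all carried a virus, and no uninfected cells were among the samples analysed here.

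Inflammatory lists held more lower than higher genes. Of 23 measured chemokines and cytokines, 11 were at least 2-fold lower, 1 was higher and 11 were not called. Ccl2, which recruits monocytes, was 6.69-fold lower (12105 to 2013), and the related Ccl7 was 10.9-fold lower, or 6.15-fold with the floor at the 60th percentile. Cxcl1, a neutrophil chemoattractant, had a log2 ratio of -2.20 in its brightest probe set and of -2.15 and -0.80 in the other 2. Il18, a cytokine of epithelia and macrophages, was the member that rose, by 8.42-fold (598 to 5601). The list's median log2 ratio was -0.64, at percentile 0.01, but this shift depended on the floor. With the floor at the 40th percentile 27 members were measured and the median was -0.109, or 0.041 relative to all genes, and without a floor 9 members were higher and 12 lower. Of 21 measured NF-kappaB targets, 3 were lower and none higher, with a median of -0.62 at percentile 0. The 3 were Lcn2 (8.502-fold) and Saa3 (7.76-fold), both acute phase genes, and the inhibitor gene Nfkbie (2.70-fold).

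The S100 family moved the other way. Of 13 measured genes on this list 4 were at least 2-fold higher and none lower, with a median log2 ratio of 0.85, or 1.01 relative to all genes, at percentile 100. The list includes S100pbp, a binding protein outside the family, and without it the 12 family members had a median of 0.91. S100a4 rose 4.82-fold, S100a16 rose 2.68-fold and S100a13 rose 2.07-fold beside S100a9. S100a8, the partner of S100a9 in calprotectin, read 17.3 on the control array and 99.04 on the array labelled KLF5. That is at least 1.80-fold, under the 2-fold limit because the control value was under the floor. With other scalings up to 7 members passed 2-fold.

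The junction and keratin list shifted upward on the array labelled KLF5, and the mesenchymal list slightly downward. Of 20 measured junction and keratin genes 3 were higher and none lower, and the median log2 ratio was 0.56 at percentile 100. Krt7, a keratin of simple and transitional epithelia, rose 7.44-fold (1746 to 14460). The tight junction gene Tjp3 just reached 2-fold (290 to 646), and Epcam rose 2.21-fold by its brightest probe set while another gave a log2 ratio of -0.20, and the mean of its probe sets was under 2-fold. Cdh1, encoding E-cadherin, read 10565 and 11129, with a log2 ratio of -0.08 that turned to 0.07 as deposited. With other scalings up to 6 members passed 2-fold, and with the mean of probe sets 2. Of 16 measured mesenchymal and matrix genes, 4 were lower and 2 higher, with a median of -0.42 at percentile 0.89. Relative to all genes this was -0.26, and -0.083 with the mean of probe sets. The smooth muscle actin gene Acta2 was 4.51-fold lower, Ccn2 3.39-fold lower and the repressor gene Snai2 2.75-fold lower. S100a4 and Col5a1 (log2 ratio 1.12, named outside the rule after its value was seen) were the members that rose.

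Genes of cell division were higher as a group. Of 35 measured mitotic genes 8 were at least 2-fold higher, none was lower, and the log2 ratio was above 0 in 35. The median was 0.72, or 0.88 relative to all genes, at percentile 100. Up to 14 members passed 2-fold with other scalings, and 6 of 34 with only probe sets without the _s_at or _x_at suffix. Cdc25c rose 2.79-fold and Cdc25b 2.52-fold, both phosphatases that activate mitotic kinases. Kif23 (2.51-fold) and Racgap1 (2.27-fold), which act together in cytokinesis, rose as well. Cdc25c was read from a probe set whose suffix marks possible cross-hybridisation, and its other probe set gave a log2 ratio of 0.96. It lost the 2-fold size without such probe sets and with the floor at the 60th percentile (log2 ratio 0.51). Kif23 lost it with the mean of its probe sets (log2 ratio 0.97). Of 36 measured genes of the G1/S transition and replication 2 were higher and none lower. These were cyclin D1 (Ccnd1), which rose 2.86-fold from 5314 to 16885 with 3 probe sets in the same direction, and Tk1, which rose 2.496-fold. The median of this list was 0.23 at percentile 100. Of 27 measured p53 targets and cell cycle inhibitors 2 were lower and none higher, with a median of -0.04 at percentile 94.7, which turned positive with other scalings. Gadd45a was 2.30-fold lower and Trp53inp1 2.19-fold lower, and neither reached 2-fold under every scaling. After loess correction 1 member of this list was higher and none lower, and after quantile normalization 1 was higher and 1 lower. Among 23 measured apoptosis regulators 4 were lower and 1 higher, with a median of -0.31 at percentile 5.61. The caspase genes Casp12 (at least 6.46-fold) and Casp4 (4.24-fold or more after centring, 3.81-fold or more as deposited, under 2-fold with the floor at the 60th percentile) were lower. The death activator Bcl2l11 was 2.30-fold lower by its brightest probe set, but the other 4 had log2 ratios from -0.72 to -0.28 and their mean with it was -0.69, under 2-fold. The kinase gene Pim1 was 2.78-fold higher. The remaining lower member was Bcl2, which opposes cell death (log2 ratio -1.16), named outside the rule after its value was seen. After quantile or loess scaling 3 members of this list were lower.

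**Figure D3:**
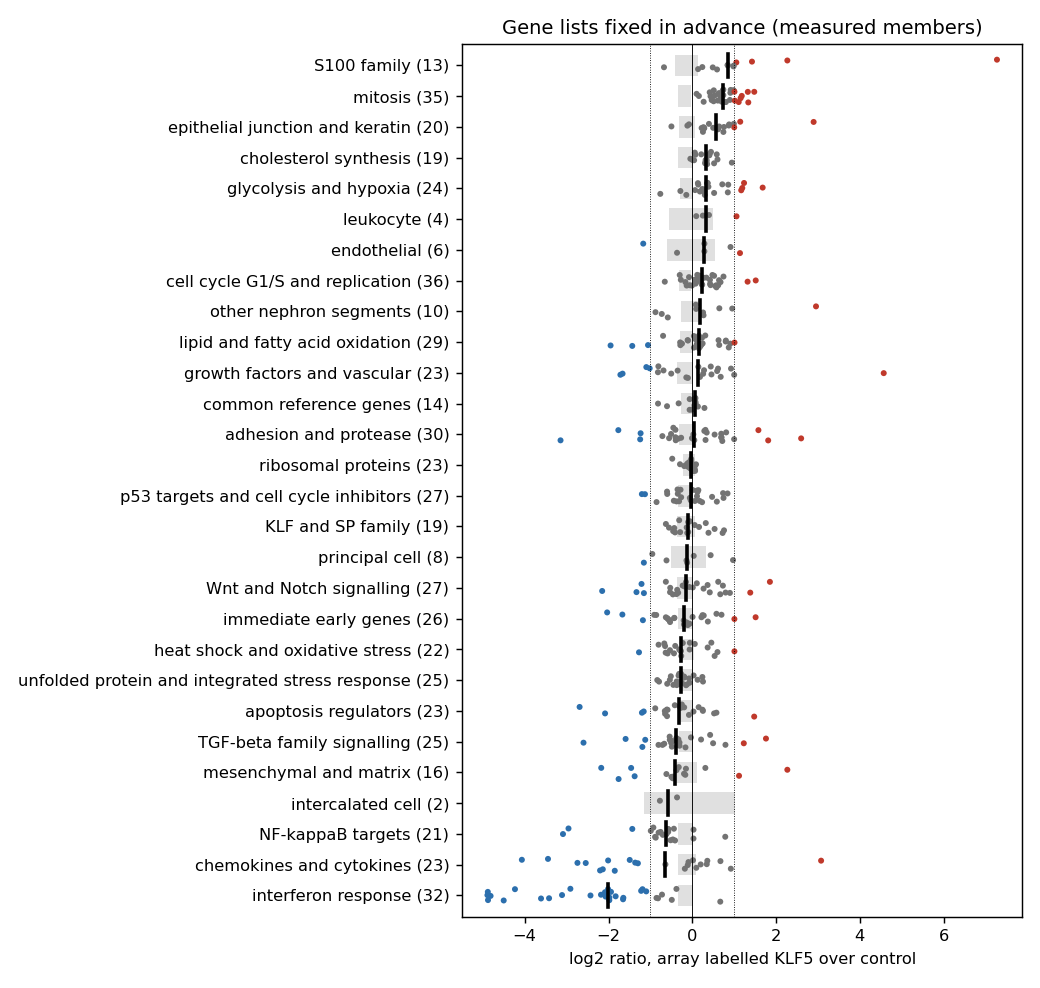
Log2 ratios of the measured members of each fixed gene list (points, number measured in parentheses), with red and blue marking changes of 2-fold or more. Black bars are medians, and grey bands hold the central 95% of medians of 10000 random lists matched on level. The interferon list has the lowest median, -2.01, and the S100 family the highest, 0.85.

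Signalling lists held changes in both directions. Of 25 measured genes of TGF-beta family signalling 4 were lower and 2 higher, with a median of -0.38 at percentile 0.57. The ligand gene Tgfb2 was 6.05-fold lower, with 4 probe sets in the same direction and a mean of 3.51-fold, and Bambi was 3.02-fold lower. Tgfbr3 rose 3.38-fold by its brightest probe set, while the other gave a log2 ratio of 0.10, and Inhbb rose 2.34-fold by its brightest probe set, with 0.69 in the other. With the mean of probe sets neither passed 2-fold, so that this list had 4 lower members and none higher. Of 23 measured growth factor and vascular genes 4 were lower and 1 higher, with a median of 0.14 at percentile 99.8. The angiogenic factor genes Angpt2 (3.29-fold), Vegfc (3.17-fold) and Pdgfb (2.14-fold) were lower, and Fgfbp1 was the member that rose. As deposited and after quantile or loess scaling the balance turned, with 3 members higher and 2 lower, Pdgfb no longer among them. Pdgfa, described as a KLF5 target in vascular cells, had a log2 ratio of 0.92 and passed 2-fold only under other scalings (log2 ratio 1.08 as deposited). Of 27 measured Wnt and Notch genes 4 were lower and 2 higher, with a median of -0.15 at percentile 65.9 whose sign changed with the scaling. Wnt7a (3.61-fold) and Wnt7b (2.61-fold) rose, Fzd8 was at least 4.44-fold lower, and Sox9 was 2.52-fold lower by its brightest probe set although another gave a log2 ratio of 0.08 and the mean of its probe sets was under 2-fold.

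Immediate early genes did not move together. Of 26 measured 3 were lower and 2 higher, with a median of -0.20 at percentile 40.3. Ccn1 (4.09-fold by its brightest probe set, 2.44-fold by the mean of all 4), Fosl1 (3.18-fold) and Myc (2.27-fold, not under every scaling) were lower, and Fos was 2.85-fold higher. After quantile or loess scaling 2 members were lower and 2 higher. Of 30 measured adhesion and protease genes 4 were lower and 3 higher, with a median of 0.04 at percentile 99.2, and under the other scalings 4 were lower and 4 higher. The integrin gene Itga1 was 8.85-fold lower by its brightest probe set and 4.92-fold by the mean with its other, and the collagenase gene Mmp13 3.40-fold lower. Timp3, a metalloprotease inhibitor with 4 probe sets in the same direction, rose 6.05-fold, and Itgb4, an integrin of hemidesmosomes, rose 3.51-fold.

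Metabolic lists shifted upward by small amounts. Of 24 measured genes of glycolysis and hypoxia 4 were higher and none lower, with a median of 0.33 at percentile 100. They were Car9 (3.20-fold, under 2-fold with the floor at the 60th percentile), Pfkp (2.35-fold), the oxygen sensor gene Egln3 (2.29-fold) and Ndrg1 (2.25-fold, with 5 probe sets in the same direction). None of 19 measured genes of cholesterol synthesis passed 2-fold, but 18 had a log2 ratio above 0, and the median was 0.34 at percentile 100. Pmvk (log2 ratio 0.94, above 1 under other scalings) and Ebp (log2 ratio 0.60) lay highest. Among 29 measured genes of lipid and fatty acid metabolism 3 were lower and 1 higher, with a median of 0.16 at percentile 99.95. As deposited and after quantile or loess scaling 2 were lower and 3 higher. Ppargc1a, a coactivator of mitochondrial genes, was 3.87-fold lower in 5 probe sets of the same direction, and Acsl4 was 2.70-fold lower. Angptl4 was 2.08-fold lower, though not under every scaling, and the fatty acid carrier gene Cd36 at least 2.01-fold higher near the floor, a call lost with the pseudocount or the mean of probe sets.

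Few stress genes passed 2-fold. None of 25 measured genes of the unfolded protein and integrated stress response passed 2-fold, and the median was -0.28 at percentile 8.03. Ddit3 (log2 ratio -0.84, with 0.28 in another probe set) and Chac1 (log2 ratio -0.79) lay lowest. Of 22 measured heat shock and oxidative stress genes 1 was lower and 1 higher, with a median of -0.28 at percentile 3.65. Hmox1 was 2.42-fold lower and Hspb1 2.01-fold higher.

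Markers of collecting duct cell types were sparsely measured. Of 17 principal cell genes 8 were measured and 1 was lower, Sgk1, a kinase of sodium transport (2.23-fold, not under every scaling). After quantile or loess scaling none was lower and 1 higher. The median was -0.13 at percentile 53.7, with a sign that changed with the scaling. The water channel gene Aqp2 read 43.5 and 52.7, under the median of each array, and so was not measurable. Of 17 intercalated cell genes 2 were measured, Car2 (log2 ratio -0.77) and Dmrt2 (log2 ratio -0.36), with a median of -0.57 at percentile 16.8. Of 22 markers of other nephron segments 10 were measured, and Aqp1, a water channel of the proximal tubule and thin limb, rose 7.74-fold (100.03 to 862), with a list median of 0.17 at percentile 96.6. Slc34a1, Slc5a2, Cubn, Pvalb and Nphs1 were under the floor on the control array alone, so their log2 ratios could only be positive. Of the other members, Aqp1 and Podxl had positive log2 ratios, and Kap, Trpm6 and Synpo negative ones. Of 24 leukocyte markers 4 were measured, with a median of 0.32 at percentile 91.3. Csf1r was 2.08-fold higher by its brightest probe set, but the other 2 gave log2 ratios of 0.27 and 0.43, and the call was lost with the mean of probe sets, the pseudocount or the floor at the 60th percentile. Of 16 endothelial markers 6 were measured, with Eng at least 2.25-fold lower, Esam at least 2.20-fold higher and a median of 0.29 at percentile 85.0. Both lay near the floor, and neither passed 2-fold with the pseudocount.

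The control lists held no gene past 2-fold under the main settings. With only probe sets without the _s_at or _x_at suffix, 1 of 20 ribosomal protein genes was lower. The 23 measured ribosomal protein genes had a median of -0.03 at percentile 79.3, with Rpl37 (log2 ratio -0.48) and Rpl14 (log2 ratio -0.29) farthest from 0 and a median sign that changed with the scaling. The 14 measured common reference genes had a median of 0.05 at percentile 93.9, with B2m (log2 ratio -0.82) and Gusb (log2 ratio -0.60) farthest from 0.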

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

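The test of RNA degradation below was chosen after the control probe sets had been seen, and the test of unspliced RNA before its result was. The flagged signals lie in probe sets outside the comparison of named genes. The manufacturer's control probe set for the mouse B1 repeat read 3188 on the control array and 7372 on the array labelled KLF5, a log2 ratio of 1.06. The control probe set for the 5′ part of 18S ribosomal RNA read 3117 and 6239, with a log2 ratio of 0.85, while its 3′ partner read 819 and 922. The control probe sets for the B2 repeat moved less, from 24959 to 28928 (log2 ratio 0.06) and from 388 to 539 (log2 ratio 0.32). Degraded RNA on the array labelled KLF5 is argued against as the cause, because it would raise the 3′ signal over the 5′ signal there. The log2 of that quotient, array labelled KLF5 minus control, was at most 0.011 over 4 control transcripts. It was -0.063 for Actb and 0.011 for Gapdh, both near the top of the intensity range where differences may be compressed. In the dimmer transcripts it was -0.001330 for pyruvate carboxylase and -0.23 for the transferrin receptor, which points away from degradation on that array. Unspliced RNA or genomic DNA on the array labelled KLF5 stays open. Measured probe sets with no gene name lay 0.13 (log2) above named ones of the same level, with a bootstrap interval of 0.086 to 0.166 that covers the spread among probe sets and not between cultures. The estimate of 0.13 lies below the 0.3 set for this cause and above the 0.1 under which it would have been excluded. The small change of the B2 repeat goes against it but does not settle it, since the brighter B2 probe set is near the top of the intensity range and the dimmer one rose. No biological explanation was tested, and an effect of KLF5 or of the virus on repeat transcripts stays open.

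Of 1980 measured probe sets with no gene name, 53 were at least 2-fold higher on the array labelled KLF5 and 77 at least 2-fold lower. The largest rise among those with no name went from 8.48 to 342, a log2 ratio of at least 2.63. The largest fall went from 847 to 27.5, with a log2 ratio of -4.10 or lower.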

How the results depend on the processing

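With 1 array per group no replicate could be left out, and no paired analysis was possible because each group held 1 array. The log2 ratio of Klf5 stayed between -0.52 and -0.27 under every alternative. Without a floor the counts were 2273 higher and 2329 lower genes, and the SD between probe sets of a gene was 1.44, since values near background then enter. With a pseudocount of 32, 264 genes were lower. At 1.5-fold 1079 genes were higher and 1684 lower, and at 3-fold 210 and 171. The counts under the other alternatives lay within 1.5 times the reported ones. Over the 28 lists and 9 alternatives, the median relative to all genes kept within its random spread in 243 cases, moved beyond it in 7 and reversed in 2. Both reversals were the chemokine and cytokine list, at 0.041 with the floor at the 40th percentile and 0.063 without a floor, settings that admit more dim members. Among lists inside that range, the relative median of the principal cell list also changed sign, between -0.200 and 0.247. The same held, by smaller amounts, for the KLF and SP, Wnt and Notch, and ribosomal protein lists. The adhesion and protease median itself turned to -0.093 without a floor, but relative to all genes it stayed at 0.061 or above. Among the named genes, values stayed within the spread between probe sets in 808 cases, moved in 92 and reversed in 1, Esam, at -0.073 with the floor at the 60th percentile. For genes a reversal was counted only past 2-fold, which leaves out Cdh1, whose log2 ratio turned from -0.08 to 0.07 as deposited. Of 86 named genes past 2-fold, 6 lost that size under at least 1 of the deposited, quantile and loess scalings, and no called gene changed sign under them. Over all 9 alternatives 19 of the 86 lost it, 9 of them with the mean of probe sets, 5 with the floor at the 60th percentile and 9 with the pseudocount, some under several. With the mean of probe sets the fold of 11 of the 86 changed by more than 1.5 times, and with the floor at the 60th percentile that of 23, of which 16 were bounds. Signal over background limits the 211 called genes that had 1 array at the floor.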

Other observations

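Of the tests below, those of the interferon pattern were chosen after its result was seen, and those of the 5 added gene lists were written before their values were. Tgfb2 and Anln were taken out of the YAP and SRF list after its first result, because their own values had been seen before that list was written. The genes of these lists named here were chosen after their values were seen. Because keratinocyte and urothelial genes led the rise, a squamous list and a urothelial list were drawn up from members not seen among the leading genes. Of 25 measured squamous genes 10 were at least 2-fold higher and 1 lower, with a median log2 ratio of 0.41, at percentile 99.99 of the random lists. Krt4, Krt5, Krt6b, Krt13, Krt16, Klk8, Gjb2, Lgals7, Sprr2d and Sprr2h were under the floor on the control array alone. Their log2 ratios could therefore only be positive. Tgm1 was under the floor on the other array alone. With the floor at the 60th percentile 16 were measured and 3 of them higher. Without a floor 16 of 41 were higher and 6 lower, with a median of 0.41. Serpinb5 (97.4 to 634), Anxa8 (5087 to 17763), the epithelial transcription factor gene Elf3 (628 to 2515) and Evpl (50.1 to 177) rose, as did Krt13, from 18.3 to 254. Ivl, the envelope precursor involucrin, went the other way with a log2 ratio of -1.99, and Sprr1a, among the brightest genes, read 24980 and 20773. Of 8 measured urothelial genes 2 were higher, Tmprss2 (350 to 1004) and Elf3 again, and the median was 0.74 at percentile 99.99. With the floor at the 40th percentile it was 0.36, and without a floor 0.26, with 2 of 16 higher and 3 lower. The urothelial shift is therefore uncertain. The squamous median and percentile rest in part on members that could only be positive. Squamous members above the floor on both arrays were split between rises and falls. Whether the stratified programme is higher as a group on the array labelled KLF5 is therefore not decided by this list. The urothelial values point upward, but both lists rest on 1 culture of each kind.

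Further groups pointed downward. Of 10 measured complement and acute phase genes other than those already named, 5 were lower and none higher, with a median of -0.99 at percentile 0. As deposited and after quantile or loess scaling 3 were lower, and without a floor 7 of 20 were lower and 3 higher, with a median of -0.31. Those lower included Cfb (5463 to 2315) and the fibrinogen gene Fgb (2335 to 680). Ankrd1, Ccn1 and Ccn2, targets of YAP and SRF, had fallen together, and 25 other measured targets had a median of -0.48 at percentile 0.01, with 20 log2 ratios below 0. Of these 25, 2 were at least 2-fold lower, among them Thbs1 (401 to 99.5), and 2 higher, Nt5e (415 to 1302) and Tpm2 (75.3 to 197). As deposited 1 was lower and the median was -0.33. The shift of this list is therefore a small one over many members. It may reflect lower YAP or SRF activity, which was not measured.

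The fall of the interferon list cannot be laid to the scaling, since the highest of its medians under 4 scalings was -1.86. Leukocytes in the control culture as carriers of these transcripts are argued against only weakly. The 26 lower genes lost a median intensity of 853, and leukocytes that brought so much would bring their own abundant transcripts too. The brightest of 23 leukocyte markers read 105.7 on the control array, and 21 lay under its median. The 4 measured ones had a median log2 ratio of 0.32. Of these, H2-Aa and Laptm5 were under the floor on the control array, so their ratios could only be positive. Cd68 (log2 ratio 0.25) and Csf1r (log2 ratio 1.06) could have fallen and did not, but both lay near the floor. The median loss was 8.07-fold the level of the brightest marker. Intensities of different probe sets compare only roughly, so this gap alone does not exclude such leukocytes. A few leukocytes that acted on the cells through secreted interferon would leave no such trace, and were not tested. Exchanged labels cannot be told apart from correct ones, because the Klf5 log2 ratio of -0.46 shows no transgene on either array. An effect of KLF5 and a difference in dose or purity between the 2 virus preparations both stay open, since no uninfected array was among the samples analysed here. Under the second, a control virus that induces more interferon could give the same values.

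Ins2 and Iapp, hormone genes of pancreatic beta cells, were bright on the control array in a kidney cell line. Ins2 read 873 and 25.6. All 4 Iapp probe sets were lower on the array labelled KLF5, which the rule for named genes required, and the brightest read 937 and 68.5. Islet cell RNA on the control array was tested on 30 other islet transcripts. Of these, 0 were measured and at least 2-fold higher on the control array, and 2 exceeded 4 times the floor there. That would have met the bound written against this explanation, but the bound was set wrongly. Of the 30, 4 had no probe set, so their level is unknown. A further 19 lay under the floor on both arrays, which goes against a large share of islet RNA. Ins2 itself stood only 17.6-fold above the floor, however, so islet transcripts less abundant than it by more than that would lie under the floor as well, and Ttr (20028) and Cpe (14580) were bright already. A small share of islet RNA could stay hidden in this way, so this explanation cannot be told apart from a regulated change. The bound was found wrong only after its result was seen.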
